A study of Mus musculus with 9 samples.

How the data were processed

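Tumours grown from 3 mouse mammary carcinoma lines, 67NR, 66cl4 and 4T1, were profiled on single-colour Affymetrix arrays. Per the labels, 1000000 viable cells of a line were injected into a mammary gland of a female BALB/c mouse, 3 mice per line, and the primary tumour was removed on day 15. Tumour tissue was isolated from sections by laser capture. Total RNA of the captured tumour areas was labelled for 1 array per mouse, which gave 9 arrays, and arrays are named here by their line and the replicate number of the label.

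The values are those the authors deposited, 1 log2 value per probe set and array for 45101 probe sets, with no detection call. That the scale is log2 was read from the values, which ran from 2.42 to 14.80. How the authors summarised probes into probe sets and how they made the arrays comparable is not given in the sources used here. The arrays had medians of 5.51 to 5.58 and 75th percentiles of 7.58 to 7.74, a range of 0.16, so the deposited log2 values were used without further scaling. A rule set before the data were examined called for quantile normalization only if the 75th percentiles differed by over 0.5. Arrays have no read depth, and their number, 3 per line, limits the precision.

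Of the probe sets, 64 were array controls. Over all probe sets, 34958 were annotated to 1 gene symbol, 932 to several and 9211 were unnamed here. Symbols came from the platform annotation and were updated through Entrez gene identifiers against a RefSeq gene table of assembly GRCm38.p6, which 34754 of the probe sets with 1 gene matched. The array's own genome build was not stated, so no coordinate is printed and the table served for names and for the chromosome a gene lies on. A gene was represented by the probe set with the highest mean over the 9 arrays among those annotated to it alone. This gave 18194 genes, 9012 of them with more than 1 probe set, and sensitivity to that choice was computed. A gene was tested when its probe set lay above the 40th percentile of its array on at least 3 arrays, which kept 13410 genes and left out 4784.

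Linear models were fitted per gene to the log2 values of all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means with no covariate, 6 residual and 3.63 prior degrees of freedom). The lines shared 1 estimate of the spread. Each pair of lines was compared two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. A moderated F-test asked which genes differed among the 3 lines. Every adjusted p in the text comes from limma, except those for the relation of hybridization controls to scan file numbers. These are Benjamini-Hochberg values of exact permutation p-values. Values are log2 differences with the standard error of the fit (SE) over 3 mice per line, and group means have the standard deviation (SD). An exact permutation test of 3 mice against 3 cannot give a p below 0.1, so the moderated model carries the tests.

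The file has no detection call, so 27 control probe sets for bacterial transcripts, whose signals were 2.72 to 5.08, were taken as background. Their highest value per array was 4.83 to 5.08. A gene at or below that value on all 3 arrays of a line was taken as not above background there, and its difference is given as a bound, "at least", computed from the brighter line's mean against the mean of, per array, the highest of these control probe sets. The bound rests on other probe sets than the gene's own and is approximate. It holds for the probe set used, and other probe sets of the gene can differ by less.

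Before the data were examined, 32 gene lists were written, 18 of tumour programmes and 14 of markers of cell types that a tumour section can hold. They held 710 genes, of which 649 were measured. Lists with at least 5 tested members, 31 of them, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The same test with a correlation estimated per list, and fry, were run beside it. Camera asks whether a list differs from the other genes, and fry whether its members move on balance one way. Members past the threshold were counted after adjustment over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time. It takes per comparison the 8 genes with the highest and the 8 with the lowest log2 difference among those changed whose 3 values per line did not overlap, passing over gene models without a symbol of their own. It adds up to 4 members with the smallest p of each list described, and 12 genes of the epithelial-mesenchymal transition whatever their result. A name outside it is marked in the text as chosen after its values were seen. Lists of 20 further mast cell genes, 10 genes of granzymes and perforin and 15 genes of tissue-resident macrophages were written later, after the comparisons had been seen. The single values of the mast cell and macrophage members had not been looked at, but Kit, Hdc, Cd163, Mrc1 and Ccl8 also belong to the earlier lists, whose summaries had, so the medians were computed again without them. Medians were also computed with genes not above background set to their bounds. Intervals of medians in the closing section are order statistics of the genes with a coverage of at least 95%, chosen after bootstrap limits had been found to move with the random seed over 20 seeds. The tests there had been decided with the bootstrap.

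The comparisons with 67NR share the same 3 arrays. Their overlap is therefore given beside the overlap of independent lists and beside the mean of 20 simulations without any effect. The pipeline was tested on simulated data with 200 of 13410 genes changed. At a log2 change of 1 it recovered 76% of 50 changed genes for 4T1 against 67NR, 70% for 66cl4 against 67NR and 84% for 4T1 against 66cl4. At a log2 change of 0.5 the shares were 40%, 26% and 24%. False calls made up 6.1%, 3.97% and 4.4% of the calls, and 0 of 50 unchanged lists were called in each comparison. The simulated genes were drawn independently and the unchanged lists were random genes. The simulation therefore does not gauge false calls for lists of correlated genes. The estimated correlation of the real lists reached 0.55, for interferon response genes among others.

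Alternatives were quantile normalization, centring on array medians, no filter and a filter at the 60th percentile, the mean of a gene's probe sets or each other probe set, a trended robust variance, a fit of the compared pair alone, a replicate block, array weights, a threshold of 0.01, each array left out and the number in the scan file's name as a covariate. The last was chosen because all 67NR arrays had higher numbers than any other array, and the labels do not say what the number means. The mean of 18 hybridization control probe sets, which detect transcripts spiked in at a fixed amount, was added as a covariate after the data were seen. It rose with that number over the 9 arrays (Pearson r = 0.87, two-sided exact permutation p = 0.0027, Spearman rho = 0.93, exact p = 0.00075, adjusted 0.0056 and 0.0045 over 6 relations). Without the 2 arrays farthest from the median number r was 0.90 (exact p = 0.004), and over the 6 arrays of 66cl4 and 4T1 it was 0.80 (exact p = 0.062). Figures were drawn with matplotlib 3.10.9, and the permutations were run in Python 3.11.15.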

Results

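The lines 67NR, 66cl4 and 4T1 were derived from a single spontaneous mouse mammary tumour and are used as a series of rising metastatic capacity. 67NR forms primary tumours that do not spread, while 66cl4 and 4T1 colonise the lung, and 4T1 reaches further organs as well. The study set the primary tumours of these lines side by side to ask what part the epithelial-mesenchymal transition plays in metastasis. In this transition epithelial cells lose their junctions and take up mesenchymal features. Expression was measured in microdissected tumour tissue of 3 mice per line, 15 days after injection, and 13410 genes were tested. Arrays of 1 line correlated with each other at r = 0.986 to 0.991 for 67NR, 0.984 to 0.989 for 66cl4 and 0.972 to 0.979 for 4T1, across genes, which are not independent replicates. Arrays of different lines correlated at 0.902 to 0.918 for 66cl4 with 67NR, 0.874 to 0.880 for 4T1 with 67NR and 0.867 to 0.881 for 4T1 with 66cl4. The mean log2 signal of the spiked hybridization controls was 11.17 ± 0.30 in 67NR, 10.86 ± 0.23 in 66cl4 and 10.46 ± 0.23 in 4T1 arrays (SD, n = 3).

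Epithelial and mesenchymal marker genes did not move together across the 3 tumours. Cdh1, encoding the adherens junction protein E-cadherin, had a log2 signal of 10.93 ± 0.17 in 4T1 tumours and was not above background in 67NR (4.09 ± 0.24) or 66cl4 tumours (4.27 ± 0.24, SD, n = 3). Cdh2, encoding N-cadherin, went the other way, with 10.59 ± 0.15 in 67NR, 9.59 ± 0.31 in 66cl4 and 4.25 ± 0.91 in 4T1 tumours, where 1 of 3 arrays lay above background. The simple epithelial keratin gene Krt8 was at 13.01 ± 0.20 in 66cl4 and 13.48 ± 0.20 in 4T1 against 6.74 ± 0.18 in 67NR tumours. Its usual partner Krt18 was at 13.39 ± 0.10 in 4T1, 5.47 ± 0.46 in 66cl4 and 4.77 ± 0.54 in 67NR tumours, and in 67NR 1 of 3 arrays lay above background. Vim and Fn1, encoding vimentin and fibronectin, had means of 13.92 to 14.13 and 13.70 to 13.83 over the 3 tumours. Neither passed the test in any comparison on these probe sets, whose means lay near the upper end of the signal range of the arrays. The other Fn1 probe set had means of 9.38 to 9.76 and did not pass the test in any comparison either. For Vim, both dimmer probe sets were lower in 4T1 than in 67NR tumours (log2 difference -0.47 and -0.53, adjusted p = 0.0161 and 0.0182). The even signal of the brightest Vim probe set thus does not show that Vim was unchanged. The captured tissue can also hold cells other than tumour cells. The Vim and Fn1 values therefore do not give the state of the tumour cells alone.

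**Figure D1:**
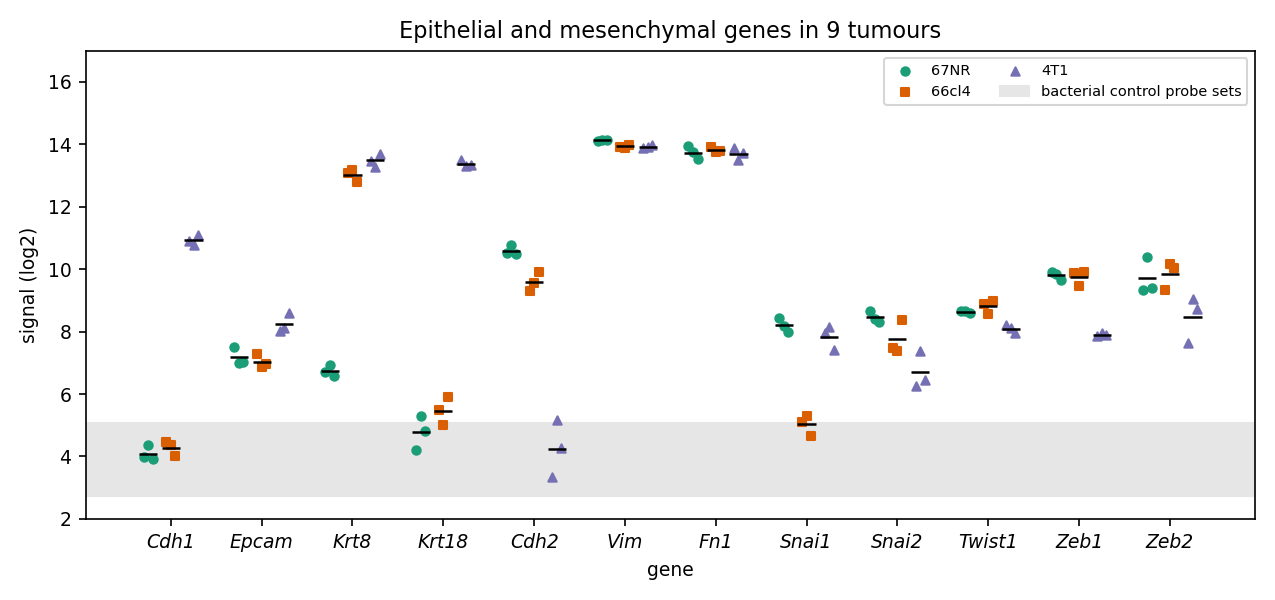
Log2 signal of 12 genes of the epithelial-mesenchymal transition on each of the 9 arrays (points, 3 per line) with the mean of the line (bar), and the range of the bacterial control probe sets shaded. Cdh1 stood at 10.93 in 4T1 against 4.09 and 4.27 in 67NR and 66cl4 tumours, Krt8 was high in both 66cl4 and 4T1, and Vim and Fn1 were near 14 throughout.

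Among the genes with the highest and lowest log2 differences between 4T1 and 67NR tumours were keratin and junction genes and genes of mast cell proteases. Krt8 was higher in 4T1 by 6.75 ± 0.15 on the log2 scale (SE, n = 3 per line, adjusted p = 4.33e-09). Krt18 was higher by 8.61 ± 0.28 (adjusted p = 3.63e-08) and Wfdc2, a secreted protein of the whey acidic protein family, by 8.12 ± 0.16 (adjusted p = 3.58e-09). For Krt18 and Wfdc2, 1 of 3 67NR arrays lay above background. Cdh1 was at least 63.4-fold higher, Npnt, encoding the matrix protein nephronectin, at least 48.1-fold, Krt7 at least 76.6-fold, the junction gene Perp at least 27.6-fold and the serine protease gene Tmprss11e at least 28.7-fold, each not above background in 67NR. The other Npnt probe sets were higher by 2.01 to 6.27 on the log2 scale. Lower in 4T1 tumours were 5 genes of mast cell proteases, Cpa3 by -6.83 ± 0.27, Tpsab1 by -6.23 ± 0.36, Cma1 by -5.85 ± 0.20, Tpsb2 by -5.80 ± 0.21 and Mcpt4 by -5.40 ± 0.24, along with Cdh2 by -6.34 ± 0.37 and the milk protein gene Csn3 by -5.53 ± 0.38. Of the 4T1 arrays, 1 of 3 was above background for Cpa3 and Cdh2, and 2 of 3 for Mcpt4 and Csn3. The tryptase and chymase genes have close relatives, and their probe sets may read more than 1 of them. Klhl4 was at least 16.1-fold lower.

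Of the list of epithelial junction genes, 19 of 26 tested members were higher in 4T1 than in 67NR tumours and 1 was lower, with the same counts adjusted over the list alone. The desmosome genes Dsp and Dsg2 were at least 19.9-fold and at least 22-fold higher. The list stood apart from other genes with a median log2 difference of 1.81, or 1.49 with genes at background set to their bounds (camera adjusted p = 7.21e-11, but adjusted p = 0.288 with an estimated correlation). All but 1 of the 16 tested epithelial regulators were higher, also when adjusted over the list alone (median 2.34, at bounds 2.32, adjusted p = 1.36e-11, but adjusted p = 0.0775 with an estimated correlation). Among them the splicing factor gene Esrp1 was at least 22.3-fold higher, the protease inhibitor gene Spint1 rose by 4.22 ± 0.19 with 2 of 3 67NR arrays above background, the membrane protease gene St14 by 3.83 ± 0.16 and the luminal transcription factor gene Gata3 by 2.22 ± 0.12. Of 9 tested keratins 5 were higher and 1 lower, the same counts adjusted over the list alone (median 4.03, adjusted p = 0.000274, but adjusted p = 0.0952 with an estimated correlation). Epcam, an epithelial adhesion gene, was higher by 1.07 ± 0.19 (adjusted p = 0.00178) on its brighter probe set, which may read other transcripts, and at least 144-fold higher on its other probe set (adjusted p = 3.18e-08).

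Of 18 tested transcription factors that drive or modulate the epithelial-mesenchymal transition, 9 were lower in 4T1 than in 67NR tumours and 1 was higher, the same adjusted over the list alone. The list did not pass camera's test (adjusted p = 0.0869). Zeb1 differed by -1.90 ± 0.13 (adjusted p = 5.2e-06), Snai2 by -1.76 ± 0.32 (0.00178), Zeb2 by -1.23 ± 0.40 (0.0331) and Twist1 by -0.55 ± 0.13 (0.00628), whereas Snai1 did not pass the test (-0.37 ± 0.22, adjusted p = 0.224). Foxc2, also on that list, was higher by 3.40 ± 0.32 with 2 of 3 67NR arrays above background. Mesenchymal genes went both ways, 12 of 27 higher and 6 lower, the same adjusted over the list alone, with no call for the list (adjusted p = 0.256). The smooth muscle gene Tagln was higher by 3.63 ± 0.37, and S100a4, a calcium-binding protein gene linked to metastasis, was lower by -2.19 ± 0.18.

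Matrix, hypoxia and immune genes differed as well between 4T1 and 67NR tumours. Of collagens and matrix genes, 17 of 34 were higher and 7 lower (18 and 8 adjusted over the list alone, median 0.75, camera adjusted p = 0.00287, but adjusted p = 0.453 with an estimated correlation). The chains of the epithelial basement membrane laminin, Lama3 and Lamb3, were at least 17.7-fold and at least 19-fold higher. Of matrix proteases and inhibitors 14 of 28 were higher and 4 lower (16 and 5 adjusted over the list alone, adjusted p = 0.0197, but adjusted p = 0.453 with an estimated correlation), with the collagenase gene Mmp13 higher by 4.77 ± 0.58. Hypoxia and glycolysis genes were higher for 23 of 28 members and lower for 1, the same adjusted over the list alone (median 1.10, adjusted p = 4.09e-09, but adjusted p = 0.406 with an estimated correlation). The hypoxia-induced genes Car9 and Egln3 rose by 4.75 ± 0.26 and 3.08 ± 0.17. Interferon response genes were higher for 20 of 31 members and lower for 0 (22 and 0 adjusted over the list alone, adjusted p = 4.7e-08, but adjusted p = 0.429 with an estimated correlation). Antigen presentation genes were higher for 12 of 18 and lower for 0, the same adjusted over the list alone (adjusted p = 3.66e-05, but adjusted p = 0.429 with an estimated correlation), with the immunoproteasome gene Psmb8 higher by 1.82 ± 0.13.

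Markers of other cell types also differed between 4T1 and 67NR tumours. Endothelial markers were lower in 4T1 for 17 of 20 members and higher for 1, the same adjusted over the list alone (median -1.52, camera adjusted p = 5.75e-08, but adjusted p = 0.35 with an estimated correlation), with the vascular cadherin gene Cdh5 at -2.11 ± 0.14. Pericyte and smooth muscle markers were lower for 8 of 13 and higher for 3, the same adjusted over the list alone (adjusted p = 0.0375, but adjusted p = 0.429 with an estimated correlation), with Rgs5 at -3.52 ± 0.37. Macrophage and monocyte markers were lower for 19 of 22 and higher for 0, the same adjusted over the list alone (median -0.91, adjusted p = 2.36e-06, but adjusted p = 0.35 with an estimated correlation), including the macrophage growth factor receptor gene Csf1r at -1.25 ± 0.17. Neutrophil markers were higher for 9 of 17 and lower for 0, the same adjusted over the list alone (median 1.06, at bounds 0.75, adjusted p = 0.00526, but adjusted p = 0.429 with an estimated correlation), with S100a9 at 2.56 ± 0.44. Csf3, the growth factor gene of neutrophils, was higher by 5.09 ± 0.21, with 2 of 3 67NR arrays above background. Proliferation genes were higher for 6 of 31 and lower for 0, and TGF-beta and BMP pathway genes for 13 of 29 with 4 lower (6 and 0, and 15 and 5, adjusted over the list alone). Both lists had an adjusted p = 0.014, but adjusted p = 0.699 and 0.35 with an estimated correlation. The share of proliferation genes called higher was no larger than that over all genes (2604 of 13410), and their median was 0.24.

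Over all genes, 5348 of 13410 (39.9%) changed between 4T1 and 67NR tumours at a limma adjusted p under 0.05, 2604 higher and 2744 lower in 4T1, and 1816 of them by at least 2-fold. The 3 values of each line did not overlap for 49.7% of genes, where chance gives 10%. Of 31 lists 14 were called, 11 higher and 3 lower, and with an estimated correlation camera called 0, although 3 lists had an unadjusted p under 0.05 and fry called 19. Fry did not call proliferation (adjusted p = 0.164), which camera also lost without 67NR replicate 1 (0.19), and did call the list of epithelial-mesenchymal transition factors (0.00641), as camera did without 67NR replicate 3 (0.0429). With the scan file number as a covariate the calls of neutrophil markers (0.306), pericyte markers (0.0602) and matrix proteases (0.105) ended. With the hybridization controls those of neutrophil (0.0704) and pericyte markers (0.0778) ended, and with the mean of probe sets that of pericyte markers (0.0545). The neutrophil median fell from 1.06 to 0.34 with the scan file number and to 0.57 with the hybridization controls. That of pericyte markers, -0.87 in the main fit, was -0.86, -0.76 and -0.5 with the scan number, the hybridization controls and the mean of probe sets. That of matrix proteases was 0.76 against 0.87. Proliferation had 0.11 without 67NR replicate 1 against 0.24. Because the scan file numbers of all 67NR arrays were above those of the others, this comparison was refitted with that number as a covariate, which called 2661 genes, 2401 of them among the 5348. With the hybridization controls as a covariate, chosen after seeing the data, 2151 were called, 2088 of them among the 5348.

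66cl4 tumours shared the rise of Krt8 with 4T1 tumours but not those of Cdh1 and Krt18. Krt8 was higher than in 67NR by 6.27 ± 0.15 (SE, n = 3 per line, adjusted p = 3.52e-08), while Cdh1 (0.18 ± 0.16, adjusted p = 0.43), Krt18 (0.70 ± 0.28, adjusted p = 0.0773, 1 of 3 67NR arrays above background) and Epcam (-0.15 ± 0.19, adjusted p = 0.593) did not pass the test. The granzyme genes Gzmg, Gzmd and Gzme, encoding proteases of cytotoxic granules, were at least 86.7-fold, at least 84.7-fold and at least 42.6-fold higher, and Gzmf rose by 6.76 ± 0.84 with 1 of 3 67NR arrays above background. Their 66cl4 arrays were uneven. Without replicate 3 the bounds for Gzmg, Gzmd and Gzme were 174-fold, 159-fold and 83.5-fold and Gzmf rose by 7.70, and without replicate 1 the bounds were 54.1-fold, 55.1-fold and 27.8-fold. These near-identical genes may share probes. Lyve1, a hyaluronan receptor of lymphatic vessels and some macrophages, was higher by 7.55 ± 0.62 with 1 of 3 67NR arrays above background, by 6.84 without 67NR replicate 1 and by 8.38 without 67NR replicate 3. The homeobox gene Prrx2 was at least 60.9-fold and the guidance factor gene Sema3e at least 24.8-fold higher. The other Sema3e probe sets were higher by 4.22 to 5.33 on the log2 scale.

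The lowest genes in 66cl4 against 67NR tumours again included those of mast cell proteases, Tpsab1 at -5.87 ± 0.36, Cpa3 at -5.59 ± 0.27 and Tpsb2 at -5.55 ± 0.21. The surface protein gene Plet1 was at least 61.3-fold lower, Ereg, encoding the growth factor epiregulin, at least 19.1-fold and Klhl4 at least 16.8-fold. The other Plet1 probe sets differed by -5.89 (adjusted p = 6.86e-06) and -0.29 (0.22). The kinase gene Dclk1 was lower by -5.77 ± 0.30 with 1 of 3 66cl4 arrays above background, and Acpp, encoding an acid phosphatase, by -5.76 ± 0.31. Among the factors of the epithelial-mesenchymal transition Snai1 was lower by -3.17 ± 0.22 (adjusted p = 7.18e-06), with 2 of 3 66cl4 arrays above background. Snai2 (-0.71 ± 0.32, adjusted p = 0.115), Twist1 (0.17 ± 0.13, 0.322), Zeb1 (-0.05 ± 0.13, 0.798), Zeb2 (0.14 ± 0.40, 0.821) and Cdh2 (adjusted p = 0.0615) did not pass the test. The other probe set of Cdh2 did, at -0.70 (adjusted p = 0.0319). Of 18 tested factors 6 were lower and 2 higher (7 and 2 adjusted over the list alone), Foxc1 among the latter by 1.84 ± 0.21, and the list was not called (adjusted p = 0.23). Of 26 junction genes 2 were higher and 1 lower (1 and 0 adjusted over the list alone), with the tight junction gene Cgn higher by 2.32 ± 0.22 and 2 of 3 67NR arrays above background. Of 16 epithelial regulators 3 were higher and 2 lower, the same adjusted over the list alone, with no call (adjusted p = 0.519). Those higher were Klf5 by 2.21 ± 0.20, Spint2 by 1.72 ± 0.20 and Gata3 by 1.43 ± 0.12.

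Genes of immune recognition were lower in 66cl4 than in 67NR tumours. Antigen presentation genes were lower for 16 of 18 members and higher for 0 (17 and 0 adjusted over the list alone, median -1.49, camera adjusted p = 1.36e-11, but adjusted p = 0.362 with an estimated correlation). Nlrc5, an activator of class I genes, was lower by -3.30 ± 0.20 and the peptide transporter gene Tap1 by -2.19 ± 0.16. Interferon response genes were lower for 19 of 31 and higher for 0, the same adjusted over the list alone (median -0.98, adjusted p = 8.67e-11, but adjusted p = 0.787 with an estimated correlation), with the interferon-induced GTPase genes Iigp1 at -3.95 ± 0.21 and Gbp3 at -2.94 ± 0.16. T and NK cell markers were lower in the same tumours for 14 of 18 members and higher for 0, the same adjusted over the list alone (median -0.93, adjusted p = 0.000264, but adjusted p = 0.787 with an estimated correlation), with Cd3g at -2.57 ± 0.37 and 2 of 3 66cl4 arrays above background. The chemokine gene Cxcl9, which attracts T cells, was lower by -4.76 ± 0.46. Macrophage and monocyte markers went both ways, 5 of 22 higher and 4 lower (6 and 4 adjusted over the list alone), with no call (adjusted p = 0.953).

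Vessel genes were lower in 66cl4 than in 67NR tumours. Endothelial markers were lower for 19 of 20 members and higher for 1, the same adjusted over the list alone (median -1.85, camera adjusted p = 2.17e-13, but adjusted p = 0.362 with an estimated correlation). Emcn, Cdh5 and Kdr, the last encoding a receptor of vascular growth factor, were lower by -2.42 ± 0.15, -2.26 ± 0.14 and -1.72 ± 0.12. Pericyte and smooth muscle markers were lower for 8 of 13 members and higher for 0, the same adjusted over the list alone (median -0.90, adjusted p = 0.000264, but adjusted p = 0.362 with an estimated correlation). The basement membrane collagen genes Col4a1 and Col4a2 were lower by -1.35 ± 0.13 and -1.81 ± 0.13 within a matrix list that was not called, with 14 of 34 lower and 9 higher (16 and 11 adjusted over the list alone, adjusted p = 0.207). Hypoxia and glycolysis genes were higher for 10 of 28 and lower for 5 (11 and 5 adjusted over the list alone, adjusted p = 0.207), and Car9 alone rose by 4.89 ± 0.26. Bmp4, a growth factor gene of the BMP pathway, was higher by 4.22 ± 0.16 with 1 of 3 67NR arrays above background.

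In total 4839 genes (36.1%) changed between 66cl4 and 67NR tumours at a limma adjusted p under 0.05, 2687 higher and 2152 lower in 66cl4, 1460 of them by at least 2-fold. The lines did not overlap for 52.5% of genes, where chance gives 10%. Of 31 lists 5 were called, all lower, and with an estimated correlation camera called 0, with 3 at an unadjusted p under 0.05, while fry called 14, among them the list of epithelial-mesenchymal transition factors (adjusted p = 0.0401). At an adjusted p under 0.01 the count of genes was 3007.

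**Figure D2:**
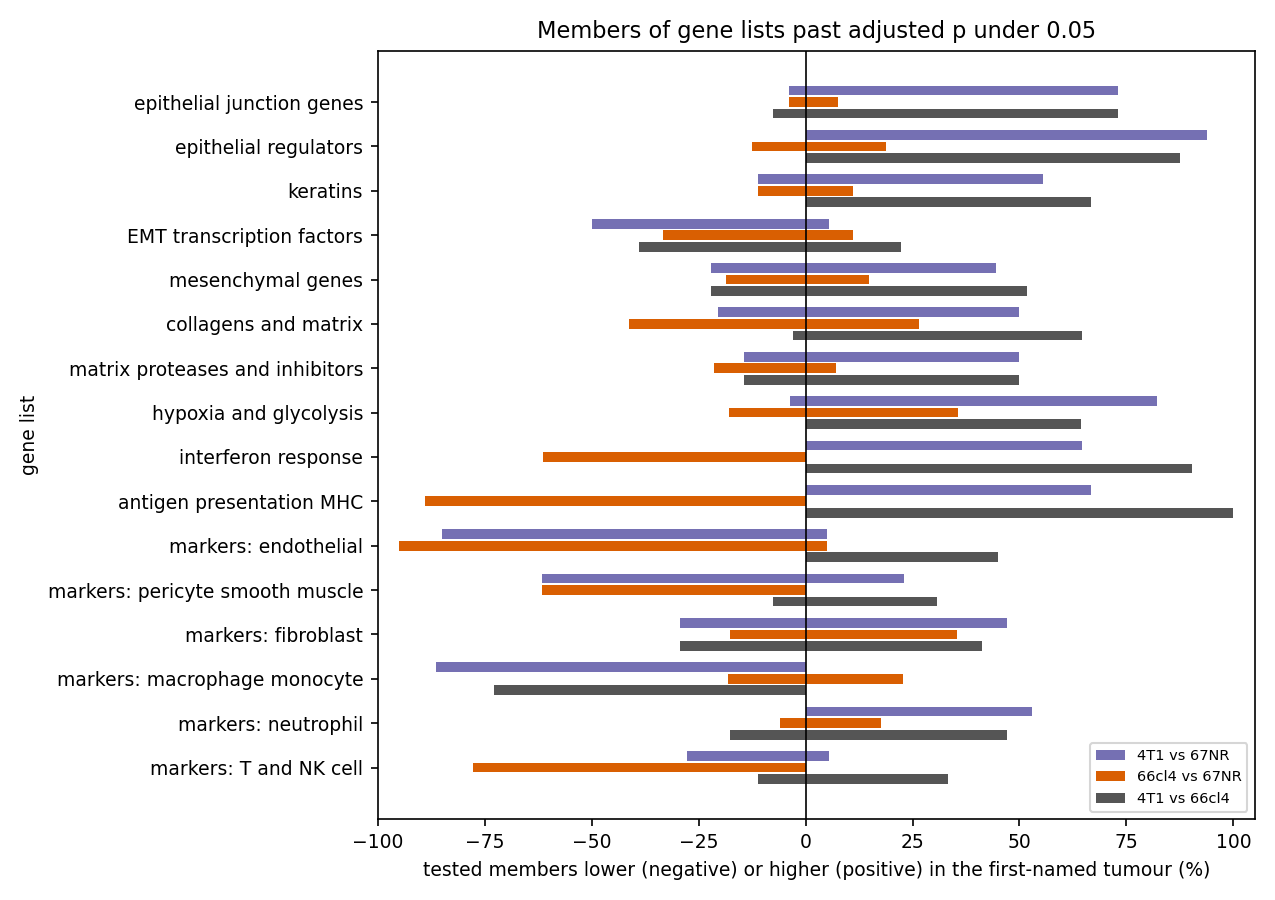
Share of the tested members (percent, horizontal axis) of 16 gene lists (vertical axis) that were higher, to the right, or lower, to the left, in the first-named tumour at an adjusted p under 0.05, with 1 bar for each of the 3 comparisons. Interferon response and antigen presentation genes point right for 4T1 against either tumour and left for 66cl4 against 67NR, and endothelial markers point left for both tumours against 67NR.

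Set against each other, 4T1 and 66cl4 tumours differed in junction, keratin and interferon genes. Krt18 was higher in 4T1 by 7.92 ± 0.28 (SE, n = 3 per line, adjusted p = 6.34e-08) and Wfdc2 by 7.82 ± 0.16 (adjusted p = 3.61e-09, 2 of 3 66cl4 arrays above background). Cdh1 was at least 64.9-fold, Krt7 at least 78.4-fold, Npnt at least 49.2-fold and Tmprss11e at least 29.4-fold higher. The other Npnt probe sets were higher by 1.97 to 6.03 on the log2 scale. Lcn2, encoding the iron carrier lipocalin 2, rose by 6.39 ± 0.59 and Pdgfrl by 6.38 ± 0.30, the latter with 1 of 3 66cl4 arrays above background. Lower in 4T1 were the matrix gene Ogn, at least 113-fold, the aldehyde dehydrogenase gene Aldh3a1, at least 61.1-fold, the protocadherin gene Pcdh17, at least 26.5-fold, the claudin gene Cldn9, at least 22.2-fold, and Cox7b2, at least 15.4-fold. The other Cldn9 probe set differed by only -2.38 on the log2 scale (adjusted p = 0.00119). Lyve1 was lower by -6.64 ± 0.62, the homeobox gene Rhox5 by -5.93 ± 0.32 and Cdh2 by -5.33 ± 0.37, with 1 of 3 4T1 arrays above background.

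Epithelial junction genes were higher in 4T1 than in 66cl4 tumours for 19 of 26 members and lower for 2 (21 and 2 adjusted over the list alone, median 1.12, camera adjusted p = 3.71e-11, but adjusted p = 0.169 with an estimated correlation). Epithelial regulators were higher for 14 of 16 and lower for 0 (15 and 0 adjusted over the list alone, median 2.00, at bounds 1.73, adjusted p = 1.09e-10, but adjusted p = 0.109 with an estimated correlation), Grhl2 among them by 3.06 ± 0.18. Keratins were higher for 6 of 9 and lower for 0, the same adjusted over the list alone (adjusted p = 0.00101, but adjusted p = 0.141 with an estimated correlation), and Krt8 differed by 0.47 ± 0.15 (adjusted p = 0.0303). Epcam was higher by 1.22 ± 0.19 (adjusted p = 0.000814) and by 7.28 on its other probe set, with 1 of 3 66cl4 arrays above background. Snai1 was higher in 4T1 by 2.81 ± 0.22 (adjusted p = 9.53e-06, 2 of 3 66cl4 arrays above background), whereas Zeb1 (-1.85 ± 0.13), Zeb2 (-1.37 ± 0.40), Snai2 (-1.05 ± 0.32) and Twist1 (-0.72 ± 0.13) were lower, with adjusted p = 5.52e-06, 0.0205, 0.0246 and 0.00138. On that list 7 of 18 factors were lower and 4 higher, the same adjusted over the list alone, with no call (adjusted p = 0.509). Mesenchymal genes were higher for 14 of 27 and lower for 6, the same adjusted over the list alone (adjusted p = 0.0334, but adjusted p = 0.534 with an estimated correlation), and Tagln rose by 3.12 ± 0.37.

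Interferon response genes were higher in 4T1 than in 66cl4 tumours for 28 of 31 members and lower for 0 (30 and 0 adjusted over the list alone, median 1.86, camera adjusted p = 3.1e-18, but adjusted p = 0.223 with an estimated correlation). All 18 antigen presentation genes were higher, also adjusted over the list alone (median 2.31, adjusted p = 2.46e-15, but adjusted p = 0.157 with an estimated correlation). Psmb9 rose by 3.43 ± 0.12, Tap1 by 3.39 ± 0.16, Gbp3 by 3.72 ± 0.16 and Zbp1, a sensor of nucleic acids, by 3.20 ± 0.13. T and NK cell markers moved with them, 6 of 18 higher and 2 lower (7 and 2 adjusted over the list alone, adjusted p = 0.037, but adjusted p = 0.534 with an estimated correlation), with Cd8a at 1.29 ± 0.25. Chemokines and cytokines were higher for 19 of 35 and lower for 8, the same adjusted over the list alone (adjusted p = 0.00361, but adjusted p = 0.496 with an estimated correlation). Of these Cxcl10, induced by interferon, rose by 4.01 ± 0.28 and Cxcl12 fell by 4.46 on the log2 scale. Macrophage markers were lower for 16 of 22 and higher for 0 (16 and 1 adjusted over the list alone, median -0.84, adjusted p = 4.92e-05, but adjusted p = 0.332 with an estimated correlation), with the mannose receptor gene Mrc1 at -2.38 ± 0.26. Neutrophil markers were higher for 8 of 17 and lower for 3 (9 and 3 adjusted over the list alone, adjusted p = 0.0334, but adjusted p = 0.496 with an estimated correlation). Endothelial markers were higher for 9 of 20 and lower for 0, the same adjusted over the list alone (adjusted p = 0.00361, but adjusted p = 0.496 with an estimated correlation).

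Matrix genes were higher in 4T1 than in 66cl4 tumours for 22 of 34 members and lower for 1 (24 and 1 adjusted over the list alone, median 1.07, camera adjusted p = 2.92e-08, but adjusted p = 0.223 with an estimated correlation). Tnc, encoding tenascin C, rose by 4.97 ± 0.51, or 4.28 without 66cl4 replicate 3, and the laminin genes Lama3 and Lamb3 were at least 18.1-fold and at least 19.4-fold higher. Matrix proteases and inhibitors were higher for 14 of 28 and lower for 4 (16 and 4 adjusted over the list alone, adjusted p = 0.003, but adjusted p = 0.432 with an estimated correlation). Mmp13 and Mmp3 rose by 6.37 ± 0.58 and 4.25 ± 0.42, with 2 of 3 66cl4 arrays above background for Mmp13. Hypoxia and glycolysis genes were higher for 18 of 28 and lower for 0, the same adjusted over the list alone (adjusted p = 4.29e-06, but adjusted p = 0.432 with an estimated correlation), Ndrg1 by 1.71 ± 0.22. Wnt and Notch pathway genes were higher for 12 of 29 and lower for 2 (13 and 2 adjusted over the list alone, adjusted p = 0.000706, but adjusted p = 0.141 with an estimated correlation), with the Notch ligand gene Jag1 at 2.15 ± 0.12. Genes tied to metastasis in the literature were higher for 15 of 33 and lower for 3 (18 and 4 adjusted over the list alone, adjusted p = 0.00203, but adjusted p = 0.332 with an estimated correlation). Lcn2 was among those higher, and Bmp4, S100a4 and Cav1 were lower, Bmp4 at least 16.1-fold, S100a4 by -2.06 ± 0.18 and Cav1, encoding the membrane scaffold caveolin 1, by -2.88 ± 0.24.

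Between 4T1 and 66cl4 tumours 5538 genes (41.3%) changed at a limma adjusted p under 0.05, 2397 higher and 3141 lower in 4T1, 1836 of them by at least 2-fold. The lines did not overlap for 50.9% of genes, where chance gives 10%. Of 31 lists 16 were called, 15 higher and 1 lower, and with an estimated correlation camera called 0, with 6 at an unadjusted p under 0.05, while fry called 19. Fry did not call T and NK cell markers (adjusted p = 0.109) or mesenchymal genes (0.142). The call of T and NK cell markers ended with the scan file number (0.209) or hybridization controls as a covariate (0.215), with no filter (0.0552), with the 60th percentile filter (0.07) and without 66cl4 replicate 2 (0.115), 66cl4 replicate 3 (0.0828) or 4T1 replicate 3 (0.0785). That of neutrophil markers ended with both covariates (0.0918 and 0.0867), with the 60th percentile filter (0.0633) and without 66cl4 replicate 3 (0.0859) or 4T1 replicate 3 (0.0753). That of mesenchymal genes ended without 66cl4 replicate 1 (0.0512), 4T1 replicate 2 (0.13) or 4T1 replicate 3 (0.0753). The medians behind these lost calls kept their direction. For T and NK cell markers, 0.49 in the main fit, the median was 0.35 with either covariate, 0.46 with no filter and 0.73 with the 60th percentile filter. Without those arrays it was 0.32 to 0.49. Neutrophil markers had 0.67 in the main fit and 0.49 to 1.1 where the call ended in these fits, mesenchymal genes 0.64 and 0.45 to 0.64. At an adjusted p under 0.01 the count of genes was 3673.

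Over the 3 tumours together, 7591 of 13410 genes (56.6%) differed in limma's F-test at an adjusted p under 0.05. Genes that set 1 tumour apart, changed by at least 2-fold against each of the others in the same direction, were most numerous in 4T1, with 552 higher and 353 lower. In 67NR tumours 365 such genes were higher and 249 lower, and in 66cl4 tumours 288 were higher and 299 lower. Cdh1, Dsp and Esrp1 belong to the 4T1 genes, and the mast cell protease genes Cpa3 and Tpsb2 were higher in 67NR than in both other tumours.

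Comparing each spreading line with 67NR asks which changes they have in common. Krt8 was higher in both, by 6.75 in 4T1 and 6.27 in 66cl4 on the log2 scale, and Car9 by 4.75 and 4.89. Cpa3 was lower by -6.83 and -5.59, Tpsab1 by -6.23 and -5.87, and Klhl4 and Ereg were lower in both. In all, 2237 genes changed in the same direction in both comparisons, 1112 higher and 1125 lower, and 506 in opposite directions. Independent lists of these sizes would share 522 higher and 440 lower genes, and simulated tumours with no effect against the same 67NR arrays shared 0. That count leaves out the real effects and does not show how much overlap the shared arrays add to them. The log2 differences correlated at r = 0.41 across genes, where shared arrays without effect gave 0.50, and their covariance was 0.28 against 0.0196 simulated, a difference of 0.26. With 3 arrays the 67NR group cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared arrays. 67NR is also the only line here that does not spread, so a gene particular to 67NR counts as shared. By at least 2-fold, 365 genes were higher and 249 lower in 67NR than in both other tumours. The overlap therefore does not tell spreading apart from other traits of 67NR. With the scan file number as a covariate 1255 genes were shared, and 1067 with the hybridization controls.

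**Figure D3:**
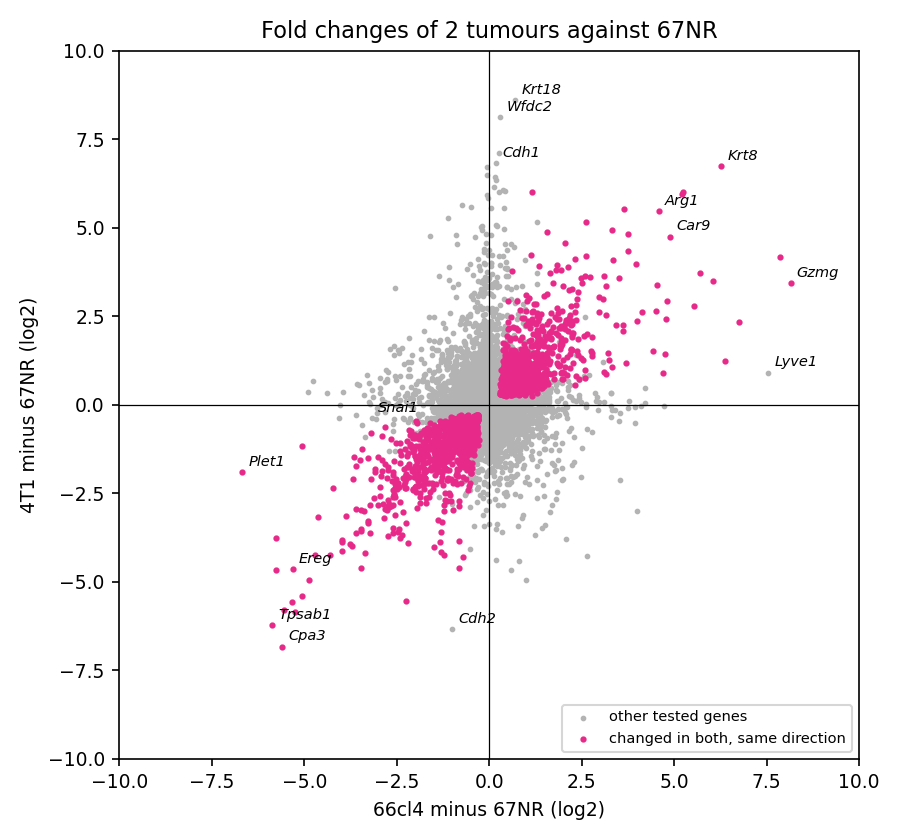
Log2 difference from 67NR for 66cl4 (horizontal axis) and 4T1 (vertical axis) for each of the 13410 genes tested, with the 2237 genes that changed in the same direction in both marked in pink. Krt8 and Car9 lie high in both tumours, Cpa3 and Tpsab1 low in both, and Cdh1 and Krt18 high in 4T1 with values of 0.18 and 0.70 in 66cl4, neither past the test there.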

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

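The tests of the scan order and of leukocytes and T and NK cells in this part were chosen after the result was seen, and so were the covariate of hybridization controls, the medians at bounds, those without genes of the earlier lists and the one over 5 granzyme and perforin genes.

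A signal lay in probe sets that the comparisons did not use. The control probe set for mouse B1 repeats had a mean of 13.82 ± 0.12 in 67NR, 13.05 ± 0.46 in 66cl4 and 12.06 ± 0.64 in 4T1 arrays (SD, n = 3), with 11.37 on the lowest array, 4T1 replicate 2, against at most 5.08 for the bacterial controls. It was lower in 4T1 than in 67NR by -1.76 ± 0.31 (adjusted p = 0.00139) and than in 66cl4 by -0.99 ± 0.31 (adjusted p = 0.0263), and 66cl4 against 67NR did not pass the test (adjusted p = 0.0767). The 5' control probe set for 18S ribosomal RNA was at 11.37 ± 1.04, 11.77 ± 0.41 and 9.53 ± 1.67 in 67NR, 66cl4 and 4T1 arrays, with 7.61 in 4T1 replicate 1. Of 10092 probe sets that were not assigned to 1 gene and were not array controls, 1108 (11%) differed among the tumours.

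Many genes differed between the tumours, 4839 to 5538 in each comparison, and the scan file numbers of all 67NR arrays were above those of the others. A trend with scan order as the whole cause is argued against by 4T1 and 66cl4, whose numbers overlap and which differed in 5538 genes, 4930 with the number as a covariate. For 4T1 against 67NR the covariate called 2661 genes, 2401 of them among the 5348, and a part played by the order of the scans in the comparisons with 67NR stays open, because number and line go together there. Of 100 splits of the 9 arrays into 3 groups of 3, 1, the real one, gave as many genes as the 7591 of the F-test, the next highest giving 1937. The same held for the 2237 genes shared by the comparisons with 67NR, where the highest other split gave 1743. A random assignment of arrays to lines is thus argued against for both counts. Every split has a shared reference group too, so for the overlap the test cannot tell how much the shared arrays add. The real lines with 66cl4 or 4T1 as the shared reference were not among the splits. The test therefore does not show that the overlap is particular to 67NR as the reference.

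For each pair of lines, 10 splits of 6 arrays are too few for a share under 0.05. The real split gave 5348 genes for 4T1 against 67NR and the highest other 1, which makes 1 split of 10 as large. For 66cl4 against 67NR the counts were 4839 and 0, and for 4T1 against 66cl4 5538 and 0, again 1 split each. Called gene lists were 14 with 17 in the highest other split (4 of 10 as large), 5 with 12 (8 of 10) and 16 with 20 (4 of 10), in the same order of comparisons. Some mixed groups of arrays thus called more lists, so the number of lists called does not set the lines apart from such groups. Camera's calls at the preset correlation are to be read with that limit.

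Interferon response and antigen presentation genes were lower in 66cl4 than in the other tumours, with a median over 46 genes of -0.94 against 67NR (interval over genes -1.54 to -0.67) and -1.90 against 4T1 (-2.48 to -1.42). A fall of all leukocytes alike is argued against by the macrophage and monocyte markers, whose median was 0.84 higher against 4T1 (lower limit 0.56). Against 67NR it was -0.01 (-0.31 to 0.61), an interval that leaves a smaller fall open, so the argument rests on the 4T1 comparison. That argument is limited, since these markers were also lower in 4T1 than in 67NR (median -0.91). B and plasma cell markers, which should fall as well, had a median of -0.92 against 67NR (1 of 9 lower, 0 higher, no call). For 4T1 against 66cl4 it was 0.56 (3 of 9 higher in 4T1, 1 lower, no call). A fall of leukocytes other than macrophages stays open. T and NK cell markers were lower in 66cl4 against both, with medians of -0.49 against 4T1 (upper limit -0.16) and -0.93 against 67NR (-1.36 to -0.58). The call of the list for 4T1 against 66cl4 ended under several alternatives, with the scan file number as a covariate for example (adjusted p = 0.209). In those fits the median stayed higher in 4T1, at 0.32 to 0.73 against 0.49 in the main fit. Over 5 granzyme and perforin genes not among those first seen, 3 of them also on that list, the median against 4T1 was -0.25, with 1 lower and 1 higher, Prf1 by 1.94 (adjusted p = 0.0145), named after its values were seen. Against 67NR 1 of these 5 genes was lower in 66cl4 and 0 higher. The granzyme genes first seen went the other way. Gzmd, Gzme, Gzmf and Gzmg were higher in 66cl4 than in 4T1 by 3.69, 2.53, 4.41 and 4.72, for Gzmg with 2 of 3 4T1 arrays above background. Against 67NR the bounds for Gzmd, Gzme and Gzmg were 84.7-fold, 42.6-fold and 86.7-fold, on uneven arrays. Fewer T and NK cells may be part of the pattern, as a hypothesis found and tested on the same data. A difference within the tumour cells of the lines stays open and was not tested.

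Mast cell genes were higher in 67NR than in the other tumours, with a median over the 6 first seen of 5.40 against 66cl4 and 5.82 against 4T1. Over 16 tested mast cell genes not among those first seen, 9 were higher and 2 lower against 66cl4, and 12 higher and 2 lower against 4T1. Their median was 1.38 against 66cl4 and 1.30 against 4T1, but 6 of them were at background in both, and set to their bounds the medians were 0.76 (-0.27 to 1.45) and 0.87 (0.57 to 1.25). Without Kit and Hdc, which the earlier lists also hold, the medians at bounds were 0.61 (-0.65 to 1.31) and 0.87 (-0.51 to 1.25). Kit, the receptor of the mast cell growth factor, was higher by 2.58 and 2.53. More mast cells in the 67NR sections may explain this, which stays open, since the interval against 66cl4 includes 0 and several of these genes are also expressed by other cells.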

How the results depend on the processing

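The covariate of hybridization controls was chosen after seeing the data. Quantile normalization, median centring, no filter, the 60th percentile filter, mean of probe sets, trended robust variance, a fit of the pair alone and array weights left every count of genes within 1.5 times, and the cause of each change below was not tested. With an estimated correlation camera called 0, 0 and 0 lists (unadjusted p under 0.05: 3, 3 and 6), and fry called 14 for 66cl4 against 67NR. The scan file number as a covariate gave 2661 genes for 4T1 against 67NR and an overlap of 1255, and hybridization controls 2151 and 1067. An adjusted p under 0.01 gave 3007 genes for 66cl4 against 67NR and 3673 for 4T1 against 66cl4. Of the results of named genes, 364 kept direction and side of the threshold with the scan number, 40 no longer passed, 5 newly passed and 3 reversed. With hybridization controls these were 367, 41, 2 and 2. Of the called lists, 5 calls ended with the scan number, 4 with hybridization controls, 3 with fry and 9 over all fits with 1 array left out. With each other probe set of these genes 320 results were counted as unchanged, 136 as no longer passing and 5 as newly passing. In that tally a change of direction was not counted apart unless both probe sets passed the threshold. It fell under unchanged where the main result had not passed, and under no longer passing where it had.

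Leaving out 1 array gave 4351 to 5192 genes for 4T1 against 67NR, 3727 to 5228 for 66cl4 against 67NR, 4554 to 5393 for 4T1 against 66cl4, 6651 to 7511 in the F-test and 1653 to 2334 shared, with 13 to 16, 5 to 6 and 14 to 17 lists.

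For the named genes, no reversed difference passed the threshold before or after, apart from those on other probe sets. Zeb2, for example, had passed at -1.23 (4T1 vs 67NR) and -1.37 (4T1 vs 66cl4). On a dim probe set, with means of 4.13 to 4.32, Zeb2 was 0.19 and 0.12, neither past the threshold. Its further probe sets were lower in 4T1 in both comparisons. Over all genes, the mean of probe sets called 1, 3 and 1 genes in the opposite direction, and 4T1 vs 66cl4 without 66cl4 replicate 1 or 3 called 1 each. With quantile normalization Vim (4T1 vs 66cl4) was 0.07. With the mean of probe sets Mb (4T1 vs 67NR) was -0.02 and Ckm (4T1 vs 66cl4) 0.04. With the scan number, Car3, Cdh1 and Fn1 (66cl4 vs 67NR) were -0.73, -0.09 and -0.05, with array weights Zeb2 (66cl4 vs 67NR) -0.11, and with hybridization controls Fn1 (66cl4 vs 67NR) -0.09 and Vim (4T1 vs 66cl4) 0.02. With 1 array left out, Fn1 (4T1 vs 67NR) was -0.14 to 0.06, and for 66cl4 vs 67NR Dsg2 was -0.19 to 0.54, Epcam -0.24 to 0.36, Fn1 -0.02 to 0.19, Zeb1 -0.13 to 0.09 and Zeb2 -0.05 to 0.48. Sprr1a (4T1 vs 66cl4) was -0.11 to 1.65 and Vim (4T1 vs 66cl4) -0.04 to 0.02.

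A block on the replicate number gave 5058, 4504 and 5180 genes, 7164 in the F-test, 2066 shared and 14, 5 and 16 lists. The correlations gave no clear sign that the numbers pair arrays. Same-number pairs correlated at -0.11 to 0.16, 2 of 9 over 0.1, and other pairs at -0.18 to 0.16. In both other lines at once, 0 of 9 arrays correlated best with their own number. Against a single other line some did, 67NR replicate 1 with 66cl4 replicate 1 for example (r = 0.16). A pseudocount does not apply to log2 values and was not run. Signal over background limits folds against dim genes to bounds.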

Other observations

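The explanations in this part were written after the patterns had been seen and before the tests were run, except that the medians at bounds, those without genes of the earlier lists and the one over 5 granzyme and perforin genes were chosen after the result was seen.

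Lyve1 and Fcna were higher in 66cl4 than in 4T1 tumours, the latter named after its values were seen. Over 15 other genes of tissue-resident macrophages, 11 were higher and 0 lower in 66cl4 than in 4T1, with a median of 2.09 (interval over genes 0.35 to 2.78), against 0.84 (lower limit 0.56) for the general macrophage list. Cbr2, Folr2 and F13a1, named after their values were seen, were higher by 4.08, 3.45 and 2.78. Without Cd163, Mrc1 and Ccl8, which the earlier lists also hold, the median over 12 genes was 2.07 (0.35 to 2.78), against 0.81 for the macrophage list without Cd163 and Mrc1. The same 15 genes were also higher in 67NR than in 4T1, 13 higher and 0 lower, with a median of 1.77, or 1.71 with genes at background set to their bounds (1.06 to 2.12). For 67NR against 66cl4 2 were higher and 6 lower, with a median of -0.42 (-1.49 to 0.39). Macrophages of this type may be less frequent in 4T1 sections than in the others. Lyve1 itself did not follow these genes. Its mean was 4.88 in 67NR, where 1 of 3 arrays lay above background, 5.79 in 4T1 and 12.43 in 66cl4 tumours. Fewer such macrophages in 4T1 sections would thus not by itself account for the Lyve1 values. The interval of the 2.09 includes 0.84, so a fall of macrophages in general stays open, as does a difference between 66cl4 and 67NR. Of the 10 granzyme and perforin genes, 5 of which had prompted the list, 1 was higher and 5 lower in 67NR than in 66cl4, with a median at bounds of -3.15 (-6.44 to 0.86), and these genes may share probes. Over the other 5 genes 1 was higher and 0 lower, with a median of 0.14, so the fall is that of the genes first seen.

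Log2 differences were not spread evenly over the chromosomes. The SD of the 20 chromosome medians was 0.129 for 4T1 against 67NR, 0.129 for 66cl4 against 67NR and 0.102 for 4T1 against 66cl4, where the highest of 1000 random assignments of 13348 genes gave 0.0308, 0.0323 and 0.0338 (permutation p = 0.001 in each, the smallest that 1000 assignments can give). After subtraction of the median over all these genes, that of chromosome 8 was 0.29 for 4T1 against 67NR. That of X was 0.37 for 66cl4 against 67NR, and that of 13 was -0.21 for 4T1 against 66cl4. The random assignments treat neighbouring genes as independent. Gains or losses of whole chromosomes in the lines may be a cause, which DNA measurements would have to test.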
